A study of Gallus gallus with 6 samples.

How the data were processed

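Total RNA from chicken embryo fibroblasts was hybridised to 6 two-colour spotted chicken arrays, per the labels. The scanner intensity values were deposited as GenePix Pro 6.0.1.22 output with local background and no normalisation, per the file headers. These files also give the percent of saturated pixels and spot flags, per the file headers. The authors also deposited a table of log2 ratios. How they normalised it is not given in the sources used here. Set against the scanner values of the same arrays, the authors' log2 values ran in the partner's direction for the 2 swapped arrays of replicate 1 and as Cy5 over Cy3 for the other arrays. Column medians were 0.0063, -0.00275, 0.0093, -0.0026, 0.006 and 0.0028. Their base and direction were settled by this comparison, and the method of centring stayed unknown. That table was complete over all arrays for 6833 probes and was used only as an alternative.

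Foreground and background medians were corrected with normexp (offset 50) and normalised within arrays by loess in limma 3.58.1 under R 4.3.3, with the 423 empty spots and 160 other control spots at weight 0 in loess. Spots flagged as bad or absent were left out. A probe was kept when its foreground exceeded the background by 2 background SD in at least 1 channel on at least 3 arrays. This left 13186 probes, of which 13175 had all 4 replicate values and were tested. Ratios were turned to one direction by the dyes in the labels. The 2 dye-swapped arrays of replicate 1 were averaged to 1 value, giving 2 values per comparison. In replicate 2 a probe's dye bias does not cancel. Linear models with empirical Bayes moderation were fitted in limma to the 4 values with 1 shared spread (2 residual and 4.46 prior degrees of freedom). Tests were two-sided, and adjusted p-values follow Benjamini-Hochberg. The ratio of 4A MafA over RCAS is the sum of both coefficients.

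The replicate numbers mark shared RNA: the file headers give the WT MafA RNA one number on the 4 arrays of replicate 1 and another on both arrays of replicate 2. These headers also settle which arrays are the dye swap. One array was scanned on another day than the rest, so that batch holds 1 array. Each array was left out in turn. This also removed the array's dye orientation or its replicate value, so an effect of the scan day could not be told apart.

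Named probes were chosen by a rule fixed before the data were examined. For WT MafA against RCAS it takes the largest log2 ratios among probes past the threshold with one sign on all 3 arrays. Where fewer than 5 passed, it takes the smallest p with one sign on all 3 arrays, given as values. Probes without a gene symbol were limited to 2 per direction. The rule and the 25 gene lists fixed at the same time were written for genes. As no identifier matched the gene table used here, the lists, the Maf family genes and the cell type markers were not tested, and probes were counted in place of genes.

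The fit was tested on simulated data with 200 changed probes among 13175. With spreads drawn from the fitted prior, false calls made up 1.27% of calls for WT MafA over RCAS and 5.66% for 4A MafA over WT MafA. With each probe's moderated spread in their place, they made up 10.2% and 8.08%, above the nominal rate. With the measured dye bias added, they made up 3.01% and 0.746% with the first spread and 1.96% for either comparison with the second. Each value comes from a single simulated data set without shared WT RNA, so differences between the comparisons are not interpreted. Shared WT RNA was simulated 100 times with normal deviates that had the variances and covariance of the replicate half-differences. These half-differences also hold dye bias. Alternatives covered background correction, foreground statistic, normalisation, scaling, filters, flags, dye terms, replicate blocks, dye-swap assignment, the prior, the threshold, the authors' table and leaving out replicates and arrays. A comparison of at least 3 independent samples per group was not available, so other splits of the samples were not counted.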

Results

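Gene expression was measured in chicken embryo fibroblasts, primary connective tissue cells, that carried either the control vector RCAS, an avian retroviral vector that replicates in these cells, or the same vector expressing MafA. MafA is a transcription factor of the basic leucine zipper family. It was present as the wild-type protein (WT MafA) or as a form that the labels name 4A MafA. The title of the series ties the study to MafA phosphorylation in transformed cells. Per the labels, 2 independent cultures were prepared for each condition. RNA was hybridised to 6 two-colour spotted arrays, 3 of which set WT MafA against RCAS and 3 of which set 4A MafA against WT MafA. In each comparison replicate 1 was hybridised to 2 arrays with the dyes swapped and replicate 2 to 1 array. No array set 4A MafA directly against RCAS.

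Each array held 16192 spots, of which 15609 were probes that each appeared once. Between 67.9% and 76.0% of probes were above background in the Cy5 channel and between 73.3% and 84.5% in the Cy3 channel. The median signal over background lay between 418 and 546 in Cy5 and between 449 and 553 in Cy3. The number of arrays limits the precision: each comparison rests on 2 replicate values. The probes carry clone-type identifiers, and the files used here do not pair them with genes. None of the 15609 identifiers occurred in the chicken gene table used here, so probes are named by identifier and gene groups could not be tested.

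The first comparison asked which transcripts differ between fibroblasts expressing WT MafA and fibroblasts carrying the control vector. WT MafA changed 738 of 13175 tested probes (limma, Benjamini-Hochberg adjusted p below 0.05), with 423 higher and 315 lower than in RCAS cells. The changed probes made up 5.60% of those tested, and 733 of the 738 had the same sign on all 3 arrays. The calls rest on these same arrays, so this agreement is largely built in. Among the probes that rose, the median log2 ratio was 0.89, and 164 probes rose at least 2-fold, 31 at least 4-fold and 7 at least 8-fold. Among those that fell, the median log2 ratio was -0.87, and 119 probes fell at least 2-fold, 12 at least 4-fold and 3 at least 8-fold.

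The probe C0004102_M8 was 18.0-fold higher with WT MafA, with a log2 ratio of 4.17 ± 0.21 (SD, n = 2; limma adjusted p = 0.00043). C0004121_C6 was 17.2-fold higher, with a log2 ratio of 4.11 ± 0.030 (SD, n = 2; limma adjusted p = 0.00039). The probe C0004101_H19 was 13.8-fold lower, with a log2 ratio of -3.79 ± 0.043 (SD, n = 2; limma adjusted p = 0.0017). C0004119_M11 was 12.8-fold lower, with a log2 ratio of -3.68 ± 0.11 (SD, n = 2; limma adjusted p = 0.0019). The WT MafA signal of C0004119_M11 was above background on 2 of the 3 arrays, so its fold is uncertain. Without background correction the log2 ratio was -2.58 for C0004119_M11 and 3.42 for C0004102_M8, below the 3.79 of C0004121_C6. C0004101_H19 carries a PCR amplification code, whose meaning the sources used here do not give, and has no value in the authors' table.

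**Figure D1:**
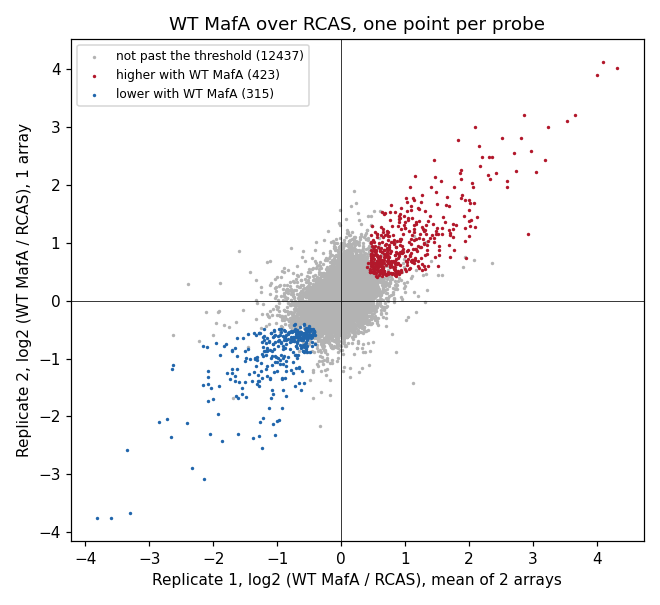
Log2 ratio of WT MafA over RCAS in replicate 1 (horizontal axis, mean of 2 dye-swapped arrays) and replicate 2 (vertical axis, 1 array), with one point per probe. The 423 probes called higher and the 315 called lower lie along the diagonal, and C0004102_M8 and C0004121_C6 stand at the upper right. The calls rest on both replicates, so the place of called probes along the diagonal is largely built in.

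Across the 13175 probes, which are not independent replicates, the WT MafA ratios of both replicates had a Pearson correlation of 0.625. The replicate 2 ratios correlated at -0.45 with the mean dye bias of both dye-swap pairs of replicate 1. A dye term in the fit of replicate values gave 403 calls, 380 of them among the 738. Subtracting the mean dye bias gave 768 (668 shared), and arrays singly with a dye term and swap block gave 811 (651 shared). Probes were also grouped by the start of their identifiers, a grouping chosen after the data were seen. The balance of higher against lower calls did not differ detectably between the 5 families of identifiers (two-sided Fisher's exact test, adjusted p = 1 for each). The family beginning with PEN held 2 tested probes and 1 call, so its test could show no difference whatever the outcome. Probes whose identifiers begin with DT40subNB were called less often than the rest, at 65 of 1582 (4.11%) against 5.81% of the other probes (two-sided Fisher's exact test, adjusted p = 0.025 over 5 families). Probes beginning with Pat were called at 119 of 1811 (6.57%), against 5.45% of the rest (adjusted p = 0.15). Several probes may represent one gene, so these tests count probes and not genes. The number of calls depended on single arrays: it was 301 without the replicate 1 array with RCAS in Cy5, 343 without the replicate 1 array with 4A MafA in Cy5, and 2227 without the replicate 1 array with WT MafA in Cy5 over RCAS. Scaling the arrays to equal spread left 314 calls. The excess of higher over lower calls turned with median centring only (314 higher, 334 lower) and without replicate 2 of WT MafA over RCAS (359 higher, 393 lower).

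The second comparison set 4A MafA directly against WT MafA. No probe passed the threshold in limma (0 of 13175, lowest adjusted p = 0.88). Across these probes, which are not independent replicates, the 4A over WT ratios of both replicates had a Pearson correlation of 0.189. It was -0.030 after the mean dye bias of both swap pairs was subtracted from each probe. The replicate 2 ratios, from 1 array, correlated at 0.68 with that dye bias. At an unadjusted p below 0.05 there were 577 probes, where chance alone gives 658.8. This count lay on either side of chance by setting: it was 1012 with the replicate block, 1128 with separate fits and 157 to 2341 without single arrays. The median 95% interval of a log2 ratio extended 0.28 to either side, and the interval lay within 2-fold in either direction for 98.9% of probes and within 1.5-fold for 88.4%. In data simulated for this comparison with 200 changed probes, 50 at each fold, the fit recovered 42 of those changed 2-fold and 10 of those changed 1.5-fold with spreads drawn from the fitted prior. With each probe's moderated spread it recovered 50 and 32. With the measured dye bias of each probe added, it recovered 33 and 2 with the first spread and 46 and 5 with the second.

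The probes of smallest p with one sign on all 3 arrays are given as values, since none passed the test. PEN_TF-10 had a log2 ratio of 4A over WT of 1.78 ± 0.68 (SD, n = 2; limma adjusted p = 0.88), or 3.45-fold. The probe Pat-19_a8 had a ratio of -1.14 ± 0.40 (SD, n = 2; limma adjusted p = 0.88), and C0004120_I14 one of -0.71 ± 0.074 (SD, n = 2; limma adjusted p = 0.97). The 4A MafA signal of C0004120_I14 was above background on 2 of the 3 arrays, so its ratio is uncertain. The WT MafA signal of C0004120_J15 was not well above background on any of the 3 arrays, and its 4A MafA signal was on 1. It is listed without a fold or ratio (limma adjusted p = 0.88).

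**Figure D2:**
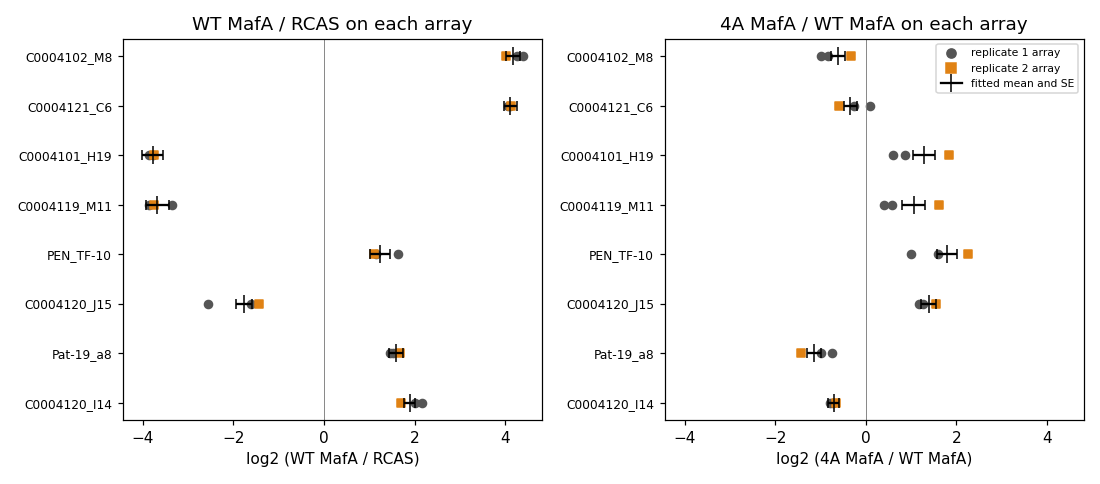
Log2 ratios of the 8 named probes on each array, for WT MafA over RCAS (left) and 4A MafA over WT MafA (right), with circles for replicate 1 arrays, squares for the replicate 2 array and bars for the fitted mean and its standard error. The first 4 probes lie near 4 or -4 on the left, and PEN_TF-10 lies highest on the right at a mean of 1.78. The points of C0004120_J15 on the right come from signals mostly not well above background.

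The comparison of 4A MafA with RCAS was indirect, as the sum of both measured ratios. It gave 58 probes past the threshold (limma, adjusted p below 0.05), 45 higher and 13 lower in 4A MafA cells. A sum of ratios has a larger error: the median standard error was 0.163, against 0.115 for WT MafA over RCAS. The main fit also took both ratios as independent, although they share WT RNA. The counts of 58 and 738 therefore do not compare the sizes of the responses. All 58 were also among the 738 probes changed by WT MafA, and all had the same sign there. The ratio of WT MafA over RCAS is part of both estimates, so this overlap and the equal signs are largely built in. C0004102_M8 was 11.7-fold higher with 4A MafA (log2 ratio 3.55 ± 0.23 SE; limma adjusted p = 0.011) and C0004121_C6 13.6-fold higher (log2 ratio 3.76 ± 0.20 SE; limma adjusted p = 0.0072). C0004101_H19 was 5.67-fold lower (log2 ratio -2.50 ± 0.33 SE; limma adjusted p = 0.049), a call lost under 10 of the 29 alternatives that tested it. C0004102_M8 was lost under 2 of 31 and C0004121_C6 under 1 of 31. The call of C0004119_M11 (log2 ratio -2.63 ± 0.35 SE, limma adjusted p = 0.049) was lost under 11 of 28. On the 3 arrays of 4A over WT, the 4A MafA signal of C0004119_M11 was above background on 1 and its WT MafA signal on none. On 1 of them its spot was flagged as not found and was kept. Its ratio of 4A over RCAS is therefore uncertain. Some alternatives repeat others: leaving out a replicate 2 array equals leaving out that replicate, and the dye term equals the replicate block. The looser threshold of 0.1 could not lose a call, so these shares understate the losses. Over the alternatives the log2 ratio ranged from 2.85 to 3.85 for C0004102_M8 and from 3.14 to 4.02 for C0004121_C6. It ranged from -3.05 to -1.63 for C0004101_H19 and from -3.20 to -1.81 for C0004119_M11. With the replicate number as a block, which stands for the WT RNA that both comparisons share, 113 probes passed. For this comparison the block is the same fit as a dye term, so shared RNA and dye bias cannot be told apart in it. The count was 0 with plain background subtraction and 6 with scaling between arrays. Leaving out single replicate 1 arrays gave 27 without WT MafA in Cy5 over RCAS, 2 without RCAS in Cy5, 12 without 4A MafA in Cy5 and 29 without WT MafA in Cy5 against 4A MafA. It was 170 without replicate 1 and 258 without replicate 2 of WT MafA over RCAS, and 10 without replicate 1 of the 4A comparison. No lower call was left with scaling between arrays, without the replicate 1 array with RCAS in Cy5, without that with 4A MafA in Cy5 or without replicate 1 of the 4A comparison.

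The 738 probes changed by WT MafA were then followed in the 4A comparison. The ratio of 4A over WT had the opposite sign to that of WT over RCAS for 587 probes (79.5%). These were mostly small shifts and not reversals. In the indirect ratio of 4A over RCAS all 738 probes kept the WT MafA direction, with a median of 85.7% of the WT log2 ratio. The share kept was below 50% for 31 probes and above 100% for 151. That indirect ratio contains the WT ratio, so the kept direction is partly built in. Among the 423 probes that rose with WT MafA the median log2 ratio of 4A over WT was -0.11, and among the 315 that fell it was 0.17. The replicates differed in this: the opposite sign was found for 56.2% of the 738 probes in replicate 1 and for 90.4% in replicate 2. Without replicate 2 of the 4A comparison, 52.4% of the probes then called had the opposite sign. The WT RNA stands in both ratios with opposite signs. In 100 simulations with the WT MafA changes present and no 4A change, the opposite sign was found for 52.4% on average and 56.5% at most. With no change in either comparison, the mean was 64.9%. The simulations drew on replicate half-differences, which hold dye bias as well as shared RNA. The dye part of the covariance of both ratios was -0.012, larger in size than the simulated -0.0038. These simulated shares therefore cannot show how much of the 79.5% comes from shared WT RNA.

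The difference between replicates was also seen when probes were chosen in one replicate and followed in the other, so that no RNA was shared. Of the 239 probes at least 2-fold higher with WT MafA in replicate 2, 51.9% had the opposite sign in the 4A ratio of replicate 1, with a median of -0.019. Of the 196 probes chosen likewise in replicate 1, 87.2% had the opposite sign in replicate 2, with a median of -0.25. For probes at least 2-fold lower, the shares were 59.4% of 133 in replicate 1 and 87.4% of 183 in replicate 2. Over the 738 probes the slope of the 4A ratio on the WT ratio of the other replicate was -0.039 for replicate 1 and -0.24 for replicate 2. For the probes that rose and those that fell it was 0.051 and -0.13 in replicate 1, and -0.096 and -0.34 in replicate 2. With 1 value per replicate, this difference was not tested.

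**Figure D3:**
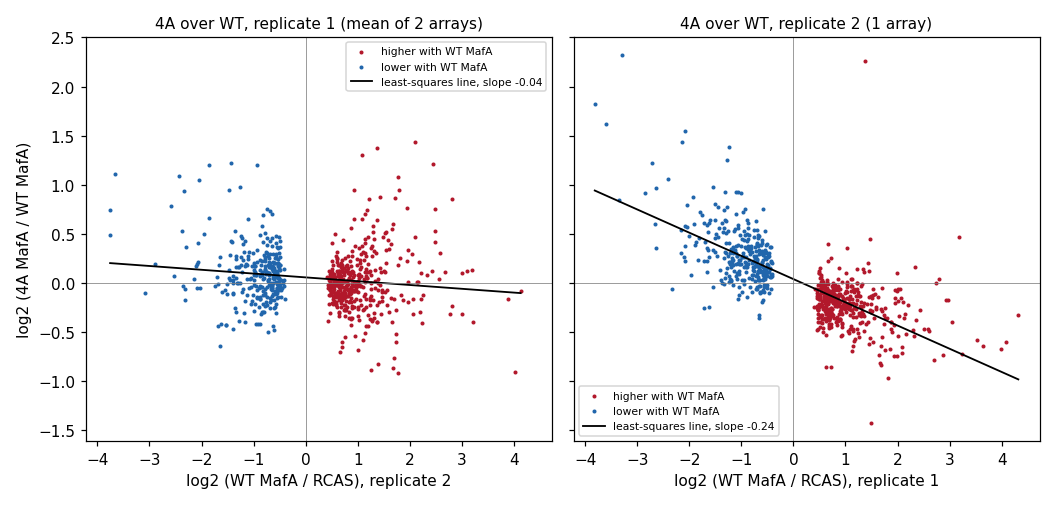
Log2 ratio of 4A MafA over WT MafA (vertical axis) against the log2 ratio of WT MafA over RCAS in the other replicate (horizontal axis) for the 738 probes changed by WT MafA, with least-squares lines. The slope was -0.04 for replicate 1 of the 4A comparison (left) and -0.24 for replicate 2 (right).

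The Pearson correlation of both ratios across all 13175 probes, which are not independent replicates, was -0.42, against -0.16 in the simulations without change. The covariance was -0.024, against -0.0038 simulated. Dye bias enters both ratios of replicate 2 with opposite signs, and after the dye bias of each probe was subtracted the covariance was -0.014. The simulated value rests on the replicate half-differences, which hold the same dye bias. It was not corrected for it, so it is no like reference for -0.014.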

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

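The 128 spots named for plant genes carry no chicken probe by name and enter no comparison. Their lowest array median was 41 over background in Cy5 and 76.5 in Cy3, against at most 9 in either channel for the spots named as empty. Between 3.65% and 5.21% of the channel signals of each plant gene's spots passed the rule for signal above background, against 2.74% of those of the empty spots and 76.9% of those of probes without a PCR code. They are listed because their medians lay above those of the empty spots, and no explanation was tested.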

How the results depend on the processing

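The alternatives that left out coded probes, subtracted the dye bias or took the arrays as independent with a dye term were chosen after seeing the data. For 4A against WT MafA limma called 0 probes under every tested setting. The rule of at least 2-fold on all arrays, which uses no test, took 2 probes there and 170 for WT MafA against RCAS. The 2 probes were PEN_TF-10 and C0004120_J15, and the signals of C0004120_J15 were mostly not well above background. The WT MafA count was 432 with plain background subtraction, 314 with scaling between arrays, 403 with a dye term in the fit of replicate values, 1229 with arrays as independent values, 1914 with a dye term added to that and 1239 at an adjusted p below 0.1. The 4A against RCAS count was, in the same order, 0, 6, 113, 235, 599 and 137. It was also 26 without the filter on dim probes and 89 with arrays singly, a dye term and a swap block. With the replicate block, for this count the same fit as the dye term of replicate values, it was again 113. It was 102 with the other dye-swap assignment, 142 with a trend and robust prior and 37 on the authors' values. The block moved no other call by over 1.5 times. The cause was not tested, except that treating arrays as independent raises the number of values and 0.1 is a looser threshold.

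Leaving out replicates or arrays gave 301 to 2227 calls for WT MafA and 2 to 258 for 4A against RCAS. The share of opposite signs ranged from 52.4% to 91.4%. It was 54.6% for probes chosen on replicate 2 with the 4A ratio from replicate 1. A comparison left with 1 value was assumed to vary like the other. For 4A against RCAS each left-out replicate or array changed the count by over 1.5 times, except replicate 2 of the 4A comparison. The 4 probes named for WT MafA kept their direction and their side of the threshold against RCAS with WT MafA wherever they were tested, and the 4 named for 4A MafA kept their direction. Without background correction the log2 ratio moved by over 1.5 times in fold for C0004102_M8 and C0004119_M11, to 3.42 and -2.58. No value is given for C0004120_J15, whose signals were mostly not well above background. Means over a gene's probes and the gene list tests were not run, as no identifier matched the gene table used here. Separate fits and the 2-fold rule give no value for 4A against RCAS.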

Other observations

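The tests on replicate differences and on dye bias in PEN_TF-10 were chosen after the result was seen. The tests of the arrays of opposite dye orientation, of the background correction and of losses against gains were written before their own results were seen, but after the patterns they bear on. Probes with identifiers beginning with DT40subNB had a median log2 brightness of 11.5, against 9.19 for those beginning with C. Over 4 classes of brightness, from dim to bright, 1.91%, 4.34%, 8.29% and 7.86% of probes were called with WT MafA. Within these classes the odds ratio of a call was 0.53 for DT40subNB probes (exact conditional test chosen after the data were seen, adjusted p = 3.3e-06) and 1.46 for probes beginning with C (adjusted p = 4.8e-05), which had been called at 5.63% against 5.53% of the rest over all classes (adjusted p = 0.83). It was 0.93 for Pat probes (adjusted p = 0.67), against 6.57% called and 5.45% of the rest over all classes, and 0.98 for DKFZ426 probes (adjusted p = 1).

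The 2 arrays of 4A over WT in replicate 1 ran against each other across probes (r = -0.28 after turning the swapped one), although they hold the same RNA. After subtraction of each probe's dye bias, estimated from the WT over RCAS pair alone, the correlation rose by 0.509 to 0.23. Dye bias of single probes is consistent with this, and the dye biases of both swap pairs correlated at r = 0.80 across probes, which are not independent replicates. An array that was not swapped would have left a negative correlation over the probes called for WT MafA, and it was 0.627 there.

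The 4A ratio had the opposite sign to the WT MafA ratio for 91.5% of the probes that rose and 88.9% of those that fell in replicate 2, and for 52.0% and 61.9% in replicate 1. Dye bias does not cancel in replicate 2, but the slope of its 4A ratio on the WT ratio of replicate 1 was -0.218 after dye bias was subtracted. Chance values of the shared WT RNA were argued against by the slope of -0.236 on the ratio from the other WT RNA, and by the 87.2% and 87.4% of opposite signs among probes chosen on replicate 1 alone. A difference between cultures, for example in the amount of MafA expressed, may remain and was not tested, as the arrays carry no measure of it that could be named here. Adjusted over the 738 probes alone, 3 passed in limma for 4A over WT (lowest adjusted p = 0.049), but that list was chosen on the same WT RNA and is not independent evidence.

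Single probes showed the opposition in both replicates: 15 of the 738 lost at least 0.5 of the WT log2 ratio in both, 13 of them with the opposite sign on all 3 arrays, and 2 gained as much. These counts divide by the mean WT ratio on which the probes were called. That ratio shares its WT RNA with both 4A ratios, which favours losses. That the 4A form weakens the response of such probes more often than it strengthens it may be put as a hypothesis. In replicate 1, with the WT ratio taken from replicate 2, 45 called probes lost at least that much and 22 gained it, a ratio of 2.05, past the 1.5 set beforehand. The called probes were chosen partly on the WT RNA of replicate 1, which favours losses, so counts free of it were added after that result was seen. Of 372 probes at least 2-fold changed in replicate 2 alone, 14 lost as much in replicate 1 and 17 gained it. In replicate 2, with the WT ratio from replicate 1, 107 called probes lost as much and 3 gained it, and 26 and 1 of the 379 probes chosen on replicate 1 alone. With 1 value per replicate this difference was not tested, and the hypothesis stays open.

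PEN_TF-10 had a ratio of 4A over WT above 0 on all 3 arrays without passing the test, and it rose with WT MafA over RCAS (2.36-fold; limma adjusted p = 0.028). Its mean log2 ratio of 4A over WT was 1.65 after dye bias was subtracted, and the lowest mean over 3 background corrections was 1.34, so neither accounts for the whole of it. Its limma adjusted p of 0.88 ranged from 0.12 to 1 over the alternatives. It is 1 of 3048 probes with a PCR amplification code, whose meaning the sources used here do not give and for which the authors' table holds no values. Among tested probes with such a code, 63 of 2395 (2.63%) were called for WT MafA, against 6.26% of the others. This pools code N, which PEN_TF-10 carries, with code M, which C0004101_H19 carries. The 2428 N probes were dim (Cy5 medians of 250 to 335) and the 620 M probes bright (1613 to 2120.5), against 490 to 644 without a code. Calls varied with brightness, and the comparison was not adjusted for it. Whether this probe differs between the MafA forms may be asked by a direct measurement, and no biological explanation was tested.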
